A study of Homo sapiens with 9 samples.

How the data were processed

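RNA sequencing counts were analysed for 9 libraries of the human iPSC line BC1, 3 each of iPSCs, freshly derived dhBMECs and dhBMECs cryopreserved for 1 year. The counts were deposited as raw whole numbers per gene, 1 row per Entrez gene ID, and were made from the reads by the authors with CASAVA, edgeR 3.28.1 and the hg38 build, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. The table held 28395 genes, of which 27745 matched a symbol in the GRCh38.p14 RefSeq annotation by Entrez ID, and 4260 had 0 counts in all libraries. Gene coordinates in the report come from that annotation. Counts below 21 were even more often than odd (63.8 to 69.2% even over the 9 libraries), against 49.3 to 51.3% among counts of 1000 or more, and the reason is not given in the sources used here.

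Groups were taken from the sample labels, and the 3 groups gave 3 comparisons. The test for single genes was the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with TMM scaling, filterByExpr by group, all 9 libraries in 1 fit, and a Benjamini-Hochberg adjusted p below 0.05. It tested 17813 genes. Fold changes are on the log2 scale with the standard error from that fit. A group with 0 counts was set to a floor of 3 counts over the group (0.0237, 0.0226 and 0.0195 CPM in iPSCs, fresh and cryopreserved dhBMECs) and its change given as a lower bound. The report gives no fold against a group with 1 to 3 counts, also where a library was left out, with 1 exception. The exception is the ranges without 1 library for NANOG and CLDN5 in cryopreserved against fresh dhBMECs, where such ends are marked. CPM values are means with the SD over 3 libraries. Depth per library was 37828957 to 55600548 counts. The libraries of a group carried different passage numbers of 1 line, so p-values measure the spread between cultures of that line. The 95% intervals come from the same fit. The 19 genes of the Y chromosome and XIST were left out of all printed tables.

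Before the data were examined, 29 gene lists with 578 genes were written, and all 578 matched the table (aliases for mitochondrially encoded genes were added later, for name matching only). They covered pluripotency, endothelial, epithelial, junction, nutrient transporter, efflux transporter, receptor-mediated transcytosis, retinoic acid response, Wnt target, neural, neural crest and placode, mesenchymal and mural, choroid plexus, blood, basement membrane and matrix, cell cycle, p53 target, heat shock, unfolded protein response, oxidative stress, hypoxia and glycolysis, cholesterol synthesis, inflammation and adhesion, interferon, YAP and SRF target, immediate early, epithelial-mesenchymal transition, mitochondrially encoded and DNA methylation genes. Lists were tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01 between members, adjusted over the lists. Genes called within a list were counted from the test over all genes, and again adjusted over the list alone.

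Genes named in the report follow a rule written before the data were examined. For each comparison it takes the 8 largest rises and the 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between libraries, then up to 4 members with the smallest adjusted p from each list, and 21 fixed markers (POU5F1, NANOG, SOX2, PECAM1, CDH5, VWF, KDR, CLDN5, OCLN, TJP1, SLC2A1, ABCB1, ABCG2, TFRC, EPCAM, CDH1, KRT8, CYP26A1, MKI67, HMOX1 and CDKN1A). Not every gene the rule takes is described. Genes outside the rule are marked where they appear. Distances between libraries used log2 CPM with a prior count of 2 over the 500 most variable genes, with an exact one-sided permutation test over the 10 splits of 6 libraries.

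The labels number the libraries of each group 1 to 3. Deviations from the group means correlated between fresh dhBMEC and iPSC libraries of equal number at 0.168, 0.2 and 0.127. Each was above 0.1, so the title number was tried as a block, a pairing that comes from the data and not from the labels. The labels pair them another way. By passage and date code, each fresh dhBMEC library was dated 10 days after the iPSC library of equal passage (68, 60 and 52), which for numbers 2 and 3 is not the library of equal number. Libraries of equal passage correlated at 0.168, -0.106 and -0.005. Such correlations over 3 libraries per group do not decide between the pairings. The main test used no block, and blocks by either pairing were tried.

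The alternatives were DESeq2 1.42.0 (Wald test), limma-voom, DESeq2 size factors, no scaling factor, no filter and a stricter filter, the 6 compared libraries alone, the title number as a block, the passage as a block (fresh dhBMECs and iPSCs only), passage as a covariate, other thresholds, other list tests (camera with an estimated correlation, fry) and leaving out each library. After the data were seen, 2 alternatives were added, leaving out both libraries farthest apart on the second component and halving all counts. Ranges printed for a list cover only the alternatives tested with camera at its preset correlation, not the estimated correlation or fry. Ranges printed for a gene leave out the runs with no scaling factor and with the stricter filter. The methods were tested on simulated data with known changes (5 simulations, 200 changed genes each). For cryopreserved against fresh dhBMECs 4.81% of the calls were false, 95.2% of the intervals held the true value, and lists raised 1.5-fold were called in 20 of 20 cases against 0 of 80 unchanged lists. The simulated genes were drawn independently, so these list values do not show the error rate of camera on correlated genes. For fresh dhBMECs against iPSCs 7.49% of the calls were false and 95.4% of the intervals held the true value. Each simulated gene was drawn around 1 mean over all 9 libraries. Far fewer genes were changed than the 9181 called in the real comparison, so these rates need not hold there. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.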

Results

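RNA was sequenced from 9 cultures of BC1, a human induced pluripotent stem cell (iPSC) line. The libraries formed 3 groups of 3. The first group was undifferentiated iPSCs. The second was freshly derived brain microvascular endothelial-like cells (dhBMECs), made from iPSC colonies by culture without bFGF and then in endothelial medium with retinoic acid. The third was dhBMECs that had been frozen in serum and dimethyl sulfoxide, stored in liquid nitrogen vapor for 1 year and thawed. Both dhBMEC groups were replated on collagen IV and fibronectin with a ROCK inhibitor before RNA was taken. Total counts per library ranged from 37828957 to 44359157 in iPSCs, from 41641059 to 46087344 in fresh dhBMECs and from 49004316 to 55600548 in cryopreserved dhBMECs. The libraries of a group carried different passage numbers of this single line, so each error covers the spread between cultures of 1 line and not between donors. Mitochondrially encoded transcripts took 3.07 ± 0.293% of counts in iPSCs, 2.93 ± 0.666% in fresh and 2.59 ± 0.939% in cryopreserved dhBMECs (SD, n = 3 each).

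The libraries separated by differentiation. The first principal component, with 78.7% of the variance, parted the 3 iPSC libraries from all 6 dhBMEC libraries, and fresh and cryopreserved libraries shared 1 side. Fresh dhBMEC replicate 2 (74.1) and cryopreserved dhBMEC replicate 2 (-54.5) lay farthest apart on the second component, which held 5.4%. Over the 500 most variable genes, the mean distance between fresh dhBMEC and iPSC libraries was 5.07 times the mean distance within these groups. The ratio was 5.19 for cryopreserved dhBMECs against iPSCs, and 0.953 for cryopreserved against fresh dhBMECs. These genes were chosen over all 9 libraries, so they weigh toward the difference between iPSCs and dhBMECs. Over all tested genes the ratios were 2.69, 2.79 and 0.985 in the same order. In exact one-sided permutation tests both comparisons with iPSCs gave p = 0.1, the smallest that 3 libraries against 3 allow, and the comparison of the dhBMEC groups gave p = 1.

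**Figure D1:**
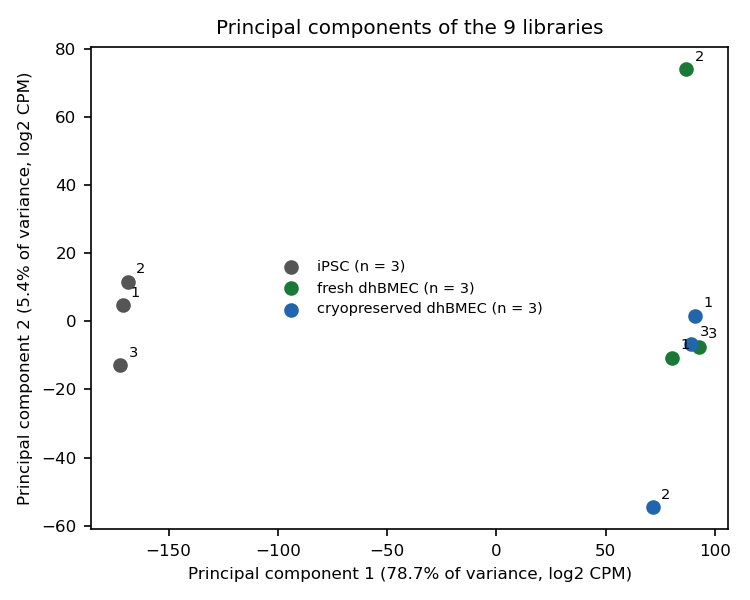
Each dot is 1 of the 9 libraries, numbered by replicate, on the first (horizontal) and second (vertical) principal component of log2 CPM, with the share of variance on each axis. The 3 iPSC libraries lie on the left and all 6 dhBMEC libraries on the right, with fresh replicate 2 at 74.1 and cryopreserved replicate 2 at -54.5 on the second component.

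The comparison of fresh dhBMECs with iPSCs asked what differentiation did to the transcriptome. Core pluripotency transcripts fell to low levels, other pluripotency transcripts stayed measurable, and most tested genes of the epithelial, retinoic acid response, neural crest and placode, and basement membrane lists rose. POU5F1 (OCT4; Entrez 5460, chromosome 6, 31164337 to 31170682, GRCh38.p14), a core pluripotency factor, was at 1414 ± 109 CPM in iPSCs and 5.38 ± 1.49 CPM in fresh dhBMECs (SD, n = 3 each), a log2 fold change of -8.04 ± 0.34 (SE, edgeR adjusted p = 1.89e-07). NANOG fell by 10.78 ± 0.72 on the log2 scale (adjusted p = 2.43e-06; -10.18 without fresh replicate 3, and without fresh replicate 2 only 2 counts were left, too few for a fold) and SOX2 fell by 5.79 ± 0.40 (adjusted p = 2.90e-06). UTF1 fell by 11.12 ± 0.33 (-11.84 without fresh replicate 1) and the de novo DNA methyltransferase DNMT3B fell by 4.59 ± 0.26. DNMT3B still held 122 ± 36.7 CPM and DPPA4 52.7 ± 9.53 CPM after a log2 fold change of -4.26 ± 0.18. LIN28A, an RNA-binding protein gene chosen after its values were seen, stayed at 669 ± 279 CPM, from 2102 ± 169 CPM in iPSCs. Of the 22 tested pluripotency genes 21 fell and none rose (camera adjusted p = 8.64e-14, and adjusted p = 0.112 with an estimated correlation). ESRG, a noncoding transcript of pluripotent cells, fell by 11.25 ± 0.41. Among the largest falls, CRIPTO, a NODAL co-receptor, went from 476 ± 24.9 to 0.0308 ± 0.0269 CPM, and HHLA1, at 122 ± 17.6 CPM in iPSCs, had 0 counts in fresh dhBMECs and so was at least 5400-fold lower. POU5F1, NANOG and CRIPTO have pseudogenes or close relatives, and reads shared with them could not be separated in the counts.

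Epithelial genes formed 1 of the clearest rises. KRT7, a simple-epithelium keratin (Entrez 3855, chromosome 12, 52233243 to 52255853), went from 4.42 ± 0.995 to 1219 ± 71.3 CPM, a log2 fold change of 8.11 ± 0.27 (edgeR adjusted p = 6.13e-08). KRT8 reached 4537 ± 259 CPM (log2 fold change 3.08 ± 0.16), KRT18 reached 2746 ± 187 CPM (2.59 ± 0.17) and KRT19 rose by 3.94 ± 0.19. KRT8 and KRT18 overlap on chromosome 12 and have pseudogenes, so their counts are uncertain. CDH1, the epithelial cadherin, rose from 509 ± 67.2 to 1413 ± 214 CPM (log2 fold change 1.47 ± 0.18, adjusted p = 1.19e-04). EPCAM was at 333 ± 29.7 and 423 ± 13.8 CPM (log2 fold change 0.34 ± 0.14, adjusted p = 0.055, and 0.0426 with limma-voom, 0.0499 with the 6 compared libraries alone and 0.0287 without both libraries extreme on the second component, from 0.0287 to 0.158 over the alternatives). Of 28 tested epithelial genes 19 rose and 1 fell (camera adjusted p = 1.34e-06, and adjusted p = 0.112 with an estimated correlation), or 20 and 1 adjusted over the list alone.

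Most regulators of the neural crest and placode list rose, and a few fell. TP63, a master regulator of stratified epithelium (Entrez 8626, chromosome 3, 189596746 to 189897276), went from 0.0378 ± 0.0466 to 155 ± 14.8 CPM (log2 fold change 11.85 ± 0.40, edgeR adjusted p = 6.13e-08). Of its 5 iPSC counts 4 were in replicate 2, and the 1 left without it was too few for a fold. TFAP2A rose by 8.85 ± 0.36 (9.44 without iPSC replicate 1) and MSX1 by 9.20 ± 0.50. TFAP2B was at 0.0150 ± 0.0260 CPM in iPSCs and 114 ± 40.0 CPM in fresh dhBMECs. Of 13 tested genes of this list 10 rose and 3 fell (camera adjusted p = 0.00236, and adjusted p = 0.112 with an estimated correlation), and the counts were equal adjusted over the list alone. The 3 that fell, named after their values were seen, were FOXD3 (26.6 ± 3.88 CPM in iPSCs and 0 counts in fresh dhBMECs) and SOX10 (3.56 ± 0.540 and 0.376 ± 0.188 CPM), both regulators of neural crest, and SIX1 (0.529 ± 0.116 and 0.0883 ± 0.0389 CPM). Among the largest rises outside these lists, HAND1 rose to 301 ± 45.2 CPM (log2 fold change 12.55 ± 0.70, with no fold without iPSC replicate 1, where 2 counts were left), and HAND2, with 0 counts in iPSCs, was at least 1200-fold higher. WNT6, a secreted Wnt ligand, was at 0.0168 ± 0.0291 CPM in iPSCs and 219 ± 87.4 CPM in fresh dhBMECs. Neural genes went the other way, with 10 of 17 lower and 1 higher (camera adjusted p = 0.00267, and adjusted p = 0.137 with an estimated correlation). SOX3 fell by 3.87 ± 0.29.

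Most tested retinoic acid response genes rose. NR2F2 (COUP-TFII; Entrez 7026, chromosome 15, 96326046 to 96340263), a nuclear receptor of venous and mesenchymal cells, went from 0.102 ± 0.0230 to 601 ± 72.7 CPM, a log2 fold change of 12.48 ± 0.26 with the smallest adjusted p of this comparison (5.24e-09, edgeR). The retinoic acid receptor RARB rose by 7.83 ± 0.21, MEIS2 by 9.08 ± 0.31 and HOXB1 by 8.85 ± 0.37 (9.51 without iPSC replicate 1). CYP26A1, which degrades retinoic acid, rose from 2.29 ± 2.11 to 200 ± 64.7 CPM (log2 fold change 6.45 ± 0.91, adjusted p = 2.59e-04; 7.52 without iPSC replicate 1). HOXB5, with 0 counts in iPSCs, was at least 1010-fold higher. Of 28 tested members 23 rose and 2 fell (camera adjusted p = 1.34e-06, and adjusted p = 0.137 with an estimated correlation), among the latter CRABP1, which binds retinoic acid and was chosen after its values were seen, from 172 ± 28.7 to 1.39 ± 0.390 CPM. Among 13 Wnt target genes 8 rose, LEF1 by 5.03 ± 0.54 (5.84 without iPSC replicate 1), and 2 fell (camera adjusted p = 0.0373, and adjusted p = 0.401 with an estimated correlation), or 9 and 2 adjusted over the list alone. The Wnt call was lost without iPSC replicate 3 (camera adjusted p = 0.0693, range 0.0145 to 0.0693 over the alternatives with the preset correlation).

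Endothelial genes moved in both directions. CDH5 (VE-cadherin; Entrez 1003, chromosome 16, 66366691 to 66404784), the endothelial adherens-junction cadherin, went from 0.139 ± 0.0872 to 29.4 ± 8.21 CPM (log2 fold change 7.67 ± 0.70, edgeR adjusted p = 1.56e-05). The endothelial transcription factor SOX7 rose by 4.44 ± 0.43. The VEGF receptors were lower, as KDR fell by 3.73 ± 0.79 to 4.83 ± 1.08 CPM (adjusted p = 0.00292) and FLT1 fell by 5.89 ± 0.47 to 2.73 ± 1.80 CPM (-6.54 without fresh replicate 1). VWF was at 0.687 ± 0.0881 CPM in iPSCs and 1.39 ± 0.143 CPM in fresh dhBMECs (adjusted p = 0.118). CLDN5, the main claudin of brain endothelium, was at 1.08 ± 0.263 and 0.160 ± 0.207 CPM (log2 fold change -2.72 ± 1.05, adjusted p = 0.0513, from 0.0111 to 0.137 over the alternatives). Without fresh replicate 3 its log2 fold change was -4.52 (adjusted p = 0.0172), and it also passed with limma-voom (0.0111), DESeq2 (0.0248), halved counts (0.019), DESeq2 size factors (0.0499) and passage as a covariate (0.0459). With the 6 compared libraries alone it passed without a block (0.0403) and with passage as a block (0.0402). Of 23 tested endothelial genes 3 rose, 7 fell and the list did not pass the camera test (adjusted p = 0.127), with equal counts adjusted over the list alone. PECAM1 (CD31) had too few counts to test, with 8 counts over the 3 iPSC libraries and 53 over the fresh dhBMEC libraries, 51 of them in replicate 1.

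**Figure D2:**
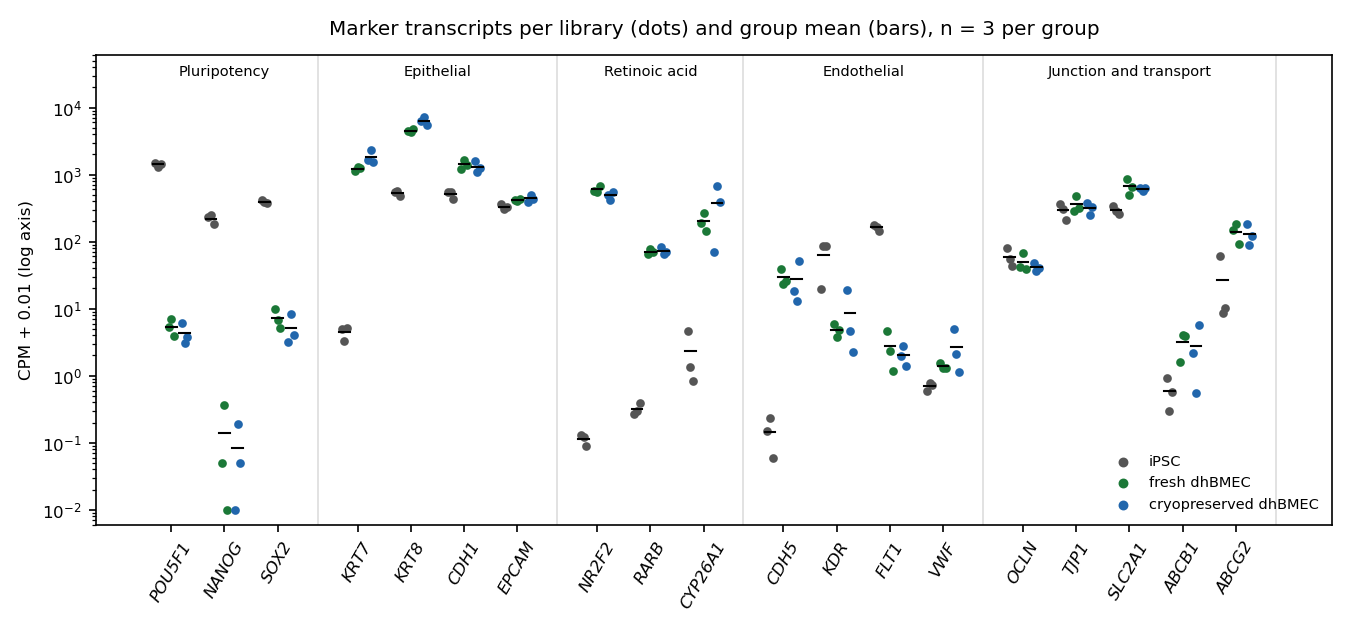
CPM plus 0.01 on a log axis for 19 marker transcripts, with 1 dot per library and a bar at the mean of each group of 3. Pluripotency transcripts are high in iPSCs alone, keratins and retinoic acid genes are high in both dhBMEC groups, and among endothelial genes CDH5 is higher and KDR and FLT1 lower in dhBMECs than in iPSCs.

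Junction, transporter and receptor genes of the blood-brain barrier were mixed. The tight-junction genes OCLN (59.7 ± 18.8 CPM in iPSCs, 49.6 ± 15.5 in fresh dhBMECs, log2 fold change -0.27 ± 0.26 and 0.01 without iPSC replicate 1, edgeR adjusted p = 0.412) and TJP1 (291 ± 78.1 and 360 ± 104, adjusted p = 0.337) did not pass the test. JAM3 fell by 0.89 ± 0.14 and CGNL1 fell by 1.48 ± 0.27. Of 23 junction genes 7 rose and 5 fell, or 8 and 7 adjusted over the list alone, and the list test was not passed (camera adjusted p = 0.774, direction up as for the median of 0.18, against a mean of -0.20). The glucose transporter SLC2A1 (GLUT1) rose from 294 ± 38.5 to 671 ± 187 CPM (log2 fold change 1.19 ± 0.20, adjusted p = 6.65e-04), SLC2A3 rose by 2.56 ± 0.22 and the amino acid transporter SLC38A5 fell by 2.91 ± 0.24. Of 25 nutrient transporters 7 rose and 9 fell (camera adjusted p = 0.373), or 8 and 9 adjusted over the list alone. The efflux pump ABCG2 (BCRP) rose from 26.5 ± 29.7 to 141 ± 45.3 CPM (log2 fold change 2.41 ± 0.68, adjusted p = 0.0129), and by 3.91 without iPSC replicate 1, which held 60.8 CPM. ABCB1 (P-glycoprotein) rose from 0.582 ± 0.304 to 3.17 ± 1.39 CPM (2.44 ± 0.78, adjusted p = 0.0236), a call lost with limma-voom (0.0567), without iPSC replicate 2 (0.0789) or 3 (0.0702) and without fresh replicate 2 (0.0588) or 3 (0.059), in a range of 0.00208 to 0.0789. Of 11 efflux transporters 3 rose and none fell (camera adjusted p = 0.389), equal adjusted over the list alone. Among receptors, the transferrin receptor TFRC fell by 0.79 ± 0.24 (adjusted p = 0.02, lost without iPSC replicate 1 at 0.0806 or fresh replicate 1 at 0.0688, range 0.00817 to 0.0806). LRP8 fell by 3.78 ± 0.31 and LDLR fell by 2.28 ± 0.32. The receptor-mediated transcytosis list had 3 members up and 4 down of 14, equal adjusted over the list alone (camera adjusted p = 0.947, direction up as for the median of 0.43, against a mean of -0.10).

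Most tested matrix transcripts rose, and mesenchymal markers were mixed. FN1 (fibronectin) reached 7221 ± 2979 CPM (log2 fold change 4.90 ± 0.40, edgeR adjusted p = 8.26e-06), LAMB1 rose by 2.65 ± 0.17, COL4A6 by 3.29 ± 0.20 and TNC by 6.13 ± 0.42. Of 22 basement membrane and matrix genes 17 rose and 1 fell (camera adjusted p = 1.84e-05, and adjusted p = 0.112 with an estimated correlation), or 17 and 2 adjusted over the list alone. Among mesenchymal and mural markers the fibrillar collagen COL3A1 rose to 2291 ± 940 CPM (12.21 ± 1.09) and LUM to 474 ± 264 CPM (11.53 ± 1.05), while THY1 fell by 4.86 ± 0.39. Without iPSC replicate 1 COL3A1 rose by 14.20 and LUM had 2 iPSC counts left, too few for a fold, while LUM rose by 10.94 without iPSC replicate 2. Of the 20 markers 12 rose and 3 fell (camera adjusted p = 0.0449, and adjusted p = 0.436 with an estimated correlation), equal adjusted over the list alone. That call was lost without iPSC replicate 2 (0.0757), iPSC replicate 3 (0.0502) or fresh replicate 2 (0.0613), with a range of 0.00784 to 0.0757 at the preset correlation. Of 16 regulators and markers of epithelial-mesenchymal transition 8 rose and 2 fell (camera adjusted p = 0.0352, and adjusted p = 0.401 with an estimated correlation), or 10 and 2 adjusted over the list alone. Of 20 YAP and SRF targets 12 rose, among them ANKRD1 (7.13 ± 0.48, and 8.02 without iPSC replicate 3) and AXL (3.42 ± 0.29), and 3 fell (camera adjusted p = 0.00894, and adjusted p = 0.436 with an estimated correlation).

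The cholesterol synthesis, cell cycle and oxidative stress lists were lower in fresh dhBMECs. All 22 tested cholesterol synthesis genes fell (camera adjusted p = 1.34e-06, and adjusted p = 0.472 with an estimated correlation). FDFT1 (squalene synthase) fell by 2.21 ± 0.31, and PCSK9 fell by 8.68 ± 0.85 from 511 ± 543 CPM. The iPSC libraries differed here, as the list's mean log2 level, relative to the 6 dhBMEC libraries, was 2.91 in iPSC replicate 1 and 1.49 and 1.16 in the others. Without iPSC replicate 1 PCSK9 fell by 7.32. Of 30 cell cycle genes 22 fell and none rose (camera adjusted p = 1.11e-04, and adjusted p = 0.436 with an estimated correlation). PLK1 fell by 1.17 ± 0.16 and CCNA2 fell by 0.98 ± 0.13, whereas MKI67 was at 246 ± 45.7 and 303 ± 66.2 CPM (edgeR adjusted p = 0.427). Of 19 oxidative stress genes 14 fell, PRDX1 by a log2 fold change of -2.24 ± 0.23, and none rose, or 1 rose and 14 fell adjusted over the list alone (camera adjusted p = 5.66e-04, and adjusted p = 0.401 with an estimated correlation). HMOX1 was at 29.7 ± 11.9 and 69.7 ± 33.8 CPM (log2 fold change 1.23 ± 0.52, adjusted p = 0.0707), and was called with the title numbers as a block (adjusted p = 0.048) and without fresh replicate 2 (0.0368), in a range of 0.00375 to 0.233. It also passed with DESeq2 (0.0305), with no filter (0.0471), without both libraries extreme on the second component (0.00617) and with the 6 compared libraries alone, both without a block (0.0297) and with passage as a block (0.00375).

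Of 20 p53 targets 9 rose and 3 fell, equal adjusted over the list alone (camera adjusted p = 0.0993, and 0.0422 without iPSC replicate 1, range 0.0422 to 0.188). The cell cycle inhibitor CDKN1A (p21) rose by 1.46 ± 0.45 (edgeR adjusted p = 0.0216, range 0.00302 to 0.0549, lost without fresh replicate 3 at 0.0549), BTG2 rose by 4.46 ± 0.39 and the exonuclease gene AEN fell by 2.08 ± 0.15. Of 22 interferon genes 11 rose and 2 fell (camera adjusted p = 0.0903, and adjusted p = 0.645 with an estimated correlation). The interferon list was called with the title numbers as a block (0.0369) and without fresh replicate 2 (0.0202) or both libraries extreme on the second component (0.00937), in a range of 0.00937 to 0.2. Its mean log2 level, relative to the mean of the 6 dhBMEC libraries, was 0.74 in fresh replicate 1 and -0.53 in fresh replicate 2. Heat shock genes (3 up, 8 down of 16, or 3 and 9 adjusted over the list alone) gave a camera adjusted p of 0.0903, and 0.0414 without iPSC replicate 3 (range 0.0414 to 0.214). Unfolded protein and integrated stress response genes (2 up, 8 down of 22) gave 0.0954, and 0.0396 without iPSC replicate 2 or 0.0392 without iPSC replicate 3 (range 0.0392 to 0.407). The remaining lists did not pass the camera test. They were hypoxia and glycolysis (5 up and 7 down of 19, or 5 and 9 adjusted over the list alone, adjusted p = 0.194), immediate early genes (9 and 4 of 18, 0.414), DNA methylation enzymes (5 and 3 of 12, 0.738), choroid plexus (5 and 4 of 10, 0.749), blood (3 and 1 of 7, 0.194), mitochondrially encoded genes (0 and 0 of 13, 0.373) and inflammation and adhesion (5 and 5 of 15, 0.889, direction down with a mean of -0.27 against a median of 0.45). Lists with no separate count here had equal counts adjusted over the list alone.

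**Figure D3:**
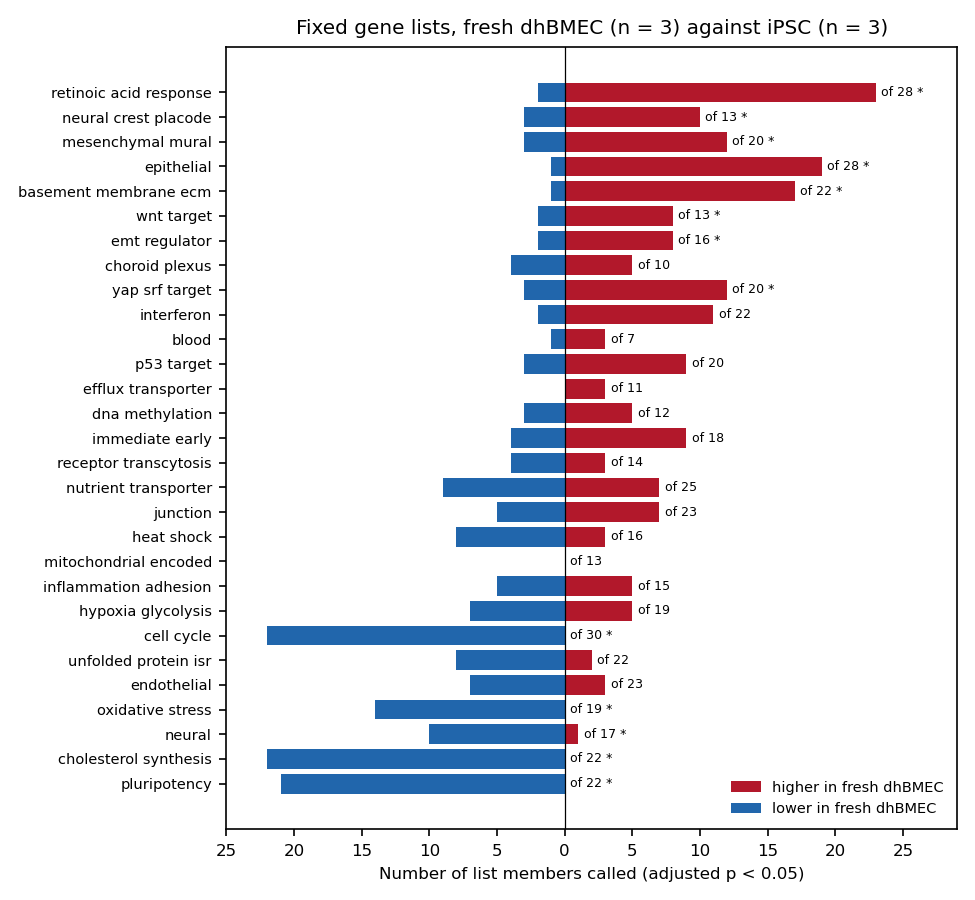
Number of members called higher (red, right) or lower (blue, left) in fresh dhBMECs than in iPSCs for each of the 29 gene lists (edgeR adjusted p below 0.05), with the tested members written beside each bar and a star where the camera test was passed with its preset correlation. Retinoic acid response has 23 members up of 28, and cholesterol synthesis has 22 down of 22.

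In all, edgeR called 9181 of 17813 tested genes (51.5%) changed in fresh dhBMECs, 4733 up and 4448 down, and 5987 of them by at least 2-fold. None of the 13 list calls held with an estimated correlation between members. A call lost in that setting does not by itself show correlated members. For the neural crest and placode list the estimate was 0.00915, below the preset 0.01. Its unadjusted camera p still went from 6.51e-04 to 0.014. By fry, which asks whether a list's genes move one way on balance and not whether they move more than other genes, 19 lists passed.

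The comparison of cryopreserved dhBMECs with iPSCs asked whether the frozen cells carried the same changes. The cryopreserved libraries carried passages 56, 60 and 64, and the iPSC libraries 68, 52 and 60. Date codes of the cryopreserved libraries were earlier, so this comparison did not separate date from differentiation and storage. No gene called in both comparisons moved in the opposite direction. POU5F1 fell by 8.36 ± 0.34 on the log2 scale to 4.31 ± 1.53 CPM (SD, n = 3; edgeR adjusted p = 1.63e-07), NANOG fell by 11.52 ± 0.75 (no fold without cryopreserved replicate 2, where 2 counts were left) and SOX2 fell by 6.24 ± 0.41. KRT7 rose by 8.71 ± 0.28 to 1846 ± 429 CPM, KRT8 by 3.56 ± 0.16 to 6352 ± 903 CPM, CDH1 by 1.36 ± 0.18 and EPCAM by 0.40 ± 0.14 to 440 ± 59.8 CPM. EPCAM's adjusted p of 0.0306 was lost without iPSC replicate 2 (0.108) or 3 (0.0821) and without cryopreserved replicate 2 (0.11) or 3 (0.0588), with the title number as a block (0.0553) and without both extreme libraries (0.0627), in a range of 0.0229 to 0.11. TP63 rose by 11.45 ± 0.40, NR2F2 by 12.17 ± 0.26, RARB by 7.87 ± 0.21, HAND1 by 12.63 ± 0.70 and CYP26A1 by 7.35 ± 0.95 to 375 ± 298 CPM. Without iPSC replicate 2 TP63 had 1 iPSC count left, and without iPSC replicate 1 HAND1 had 2, both too few for a fold. HAND1 rose by 12.04 without iPSC replicate 2 and 11.98 without cryopreserved replicate 1. CYP26A1 rose by 8.43 without iPSC replicate 1 and 6.65 without cryopreserved replicate 2. HAND2 and HOXB5, at 0 counts in iPSCs, were at least 729-fold and 972-fold higher.

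All 22 tested pluripotency genes fell (camera adjusted p = 2.80e-14, and adjusted p = 0.0981 with an estimated correlation). Of 28 epithelial genes 21 rose and 1 fell (8.28e-07, and adjusted p = 0.0981 with an estimated correlation), of 28 retinoic acid genes 23 rose and 2 fell (1.19e-06, and adjusted p = 0.156 with an estimated correlation), and of 13 neural crest and placode genes 10 rose and 3 fell (0.00319, and adjusted p = 0.0981 with an estimated correlation). Basement membrane and matrix genes had 17 up and 1 down of 22, or 17 and 2 adjusted over the list alone (5.74e-06, and adjusted p = 0.0981 with an estimated correlation). FN1 rose by 4.71 ± 0.40, COL3A1 by 12.19 ± 1.09 and LUM by 11.78 ± 1.05. Without iPSC replicate 1 COL3A1 rose by 14.18 and LUM had 2 iPSC counts left, too few for a fold, while LUM rose by 11.18 without iPSC replicate 2 and 11.08 without cryopreserved replicate 1. Mesenchymal and mural markers had 14 up and 3 down of 20 (0.0169, and adjusted p = 0.370 with an estimated correlation). Epithelial-mesenchymal transition genes had 11 up and 2 down of 16, or 13 and 2 adjusted over the list alone (0.00895, and adjusted p = 0.310 with an estimated correlation). YAP and SRF targets had 11 up and 2 down of 20, or 13 and 3 adjusted over the list alone (0.00157, and adjusted p = 0.370 with an estimated correlation). Wnt targets had 9 up and 2 down of 13, or 10 and 2 adjusted over the list alone (0.0436, and adjusted p = 0.397 with an estimated correlation), a call lost without iPSC replicate 1 (0.0565) or 3 (0.0681) and without both libraries extreme on the second component (0.0594), range 0.0191 to 0.0681.

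Neural genes fell in 10 of 17 and rose in 2 (0.00534, and adjusted p = 0.163 with an estimated correlation). All 22 cholesterol synthesis genes fell (camera adjusted p = 2.38e-05, and adjusted p = 0.546 with an estimated correlation), FDFT1 by a log2 fold change of -1.62 ± 0.31 and LDLR by -1.70 ± 0.32, and by -1.10 and -1.13 without iPSC replicate 1. Cell cycle genes had 21 of 30 down and none up (2.38e-05, and adjusted p = 0.413 with an estimated correlation). Oxidative stress genes had 10 down and 1 up of 19, or 12 and 1 adjusted over the list alone (0.0028, and adjusted p = 0.397 with an estimated correlation). The p53 target list passed the test here, with 12 up and 2 down of 20, or 13 and 2 adjusted over the list alone (0.011, and adjusted p = 0.546 with an estimated correlation). CDKN1A rose by 2.11 ± 0.46 to 81.9 ± 41.3 CPM (edgeR adjusted p = 0.00366). HMOX1 rose by 1.37 ± 0.52 (adjusted p = 0.0494), a call lost without iPSC replicate 2 (0.129) or 3 (0.15) and without cryopreserved replicate 1 (0.0812) or 3 (0.23, log2 fold change 0.77), with limma-voom (0.0951) and with DESeq2 size factors (0.0507), range 0.0033 to 0.23.

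Among endothelial and barrier genes, CDH5 rose by 7.58 ± 0.70 to 27.6 ± 21.2 CPM (edgeR adjusted p = 1.67e-05; 6.75 without cryopreserved replicate 3), SOX7 by 4.58 ± 0.44, and VWF by 1.97 ± 0.51 to 2.71 ± 1.95 CPM (adjusted p = 0.0087). Without cryopreserved replicate 1, which held 4.89 CPM, VWF rose by 1.24 (adjusted p = 0.0465, range 5.78e-04 to 0.0465). KDR fell by 2.90 ± 0.76, FLT1 fell by 6.32 ± 0.48, and CLDN5 fell by 4.45 ± 1.19 to 0.0487 ± 0.0534 CPM (adjusted p = 0.0102). KDR fell by 4.21 without cryopreserved replicate 1, where CLDN5 had 2 counts left, too few for a fold, and CLDN5 fell by 3.84 without cryopreserved replicate 3. Of 23 endothelial genes 5 rose and 9 fell (camera adjusted p = 0.136). SLC2A1 rose by 1.05 ± 0.20 (adjusted p = 0.00142) and TFRC fell by 1.26 ± 0.24 (adjusted p = 0.00181). ABCG2 rose by 2.30 ± 0.67 (adjusted p = 0.0161, lost without iPSC replicate 3 at 0.053 or cryopreserved replicate 1 at 0.0505, range 9.44e-05 to 0.053), and by 3.80 without iPSC replicate 1. ABCB1 rose by 2.26 ± 0.77 (adjusted p = 0.0323, lost without iPSC replicate 2 at 0.103 or 3 at 0.0875 and without cryopreserved replicate 3 at 0.183 with a log2 fold change of 1.23, with limma-voom at 0.139 and with the title number as a block at 0.0629, range 0.00497 to 0.183). OCLN (41.8 ± 5.60 CPM, adjusted p = 0.121) and TJP1 (317 ± 61.7 CPM, adjusted p = 0.703) did not pass the test, and the sign for TJP1 turned from 0.13 to -0.07 without iPSC replicate 3. PECAM1 had 8 counts over the 3 cryopreserved libraries.

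The other lists did not pass the camera test in cryopreserved dhBMECs against iPSCs. They were junctions (9 up and 6 down of 23, adjusted p = 0.735), nutrient transporters (8 and 9 of 25, 0.269), efflux transporters (3 and 1 of 11, or 0 and 0 adjusted over the list alone, 0.730), receptor-mediated transcytosis (4 and 4 of 14, 0.912), choroid plexus (5 and 4 of 10, 0.730), blood (3 and 2 of 7, 0.183), heat shock (3 and 9 of 16, 0.0713), unfolded protein response (2 and 6 of 22, 0.232), hypoxia and glycolysis (3 and 7 of 19, 0.413), inflammation (5 and 5 of 15, 0.912), interferon (8 and 2 of 22, 0.139), immediate early genes (8 and 3 of 18, 0.269), mitochondrially encoded genes (0 and 0 of 13, 0.224) and DNA methylation (5 and 4 of 12, 0.799). Leaving out 1 library brought 3 of them past the test. Heat shock was at 0.0326 without iPSC replicate 3 and 0.0437 without cryopreserved replicate 2 (range 0.0326 to 0.16), interferon at 0.0498 without cryopreserved replicate 2 (range 0.0363 to 0.236), and mitochondrially encoded genes at 0.00374 without cryopreserved replicate 1 (range 0.00374 to 0.65). Test and median (up) went against the mean for junctions (0.13, mean -0.17) and receptor-mediated transcytosis (0.22, mean -0.06), and test and mean (down) went against the median for hypoxia (mean -0.20, median 0.08) and inflammation (mean -0.41, median 0.21). Lists with no separate count had equal counts adjusted over the list alone.

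In cryopreserved dhBMECs edgeR called 9051 genes (50.8%) changed against iPSCs, 4679 up and 4372 down, of which 5955 by at least 2-fold. With fresh dhBMECs, 4206 of the genes called higher and 3870 of those called lower were shared, against 1243 and 1092 for independent lists of these lengths, and 0 genes were called in opposite directions. Across the 17813 genes, which are not independent replicates, the log2 fold changes of both comparisons correlated at 0.967, with a covariance of 4.81. In 20 simulations of unchanged groups set against shared simulated controls the correlation averaged 0.510 and the covariance 0.131, so the covariance exceeded the simulated mean by 4.68. The simulations shared 0.05 calls on average. The 3 iPSC libraries could not be split with at least 2 on each side, and part of the excess in shared calls may come from the shared controls.

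**Figure D4:**
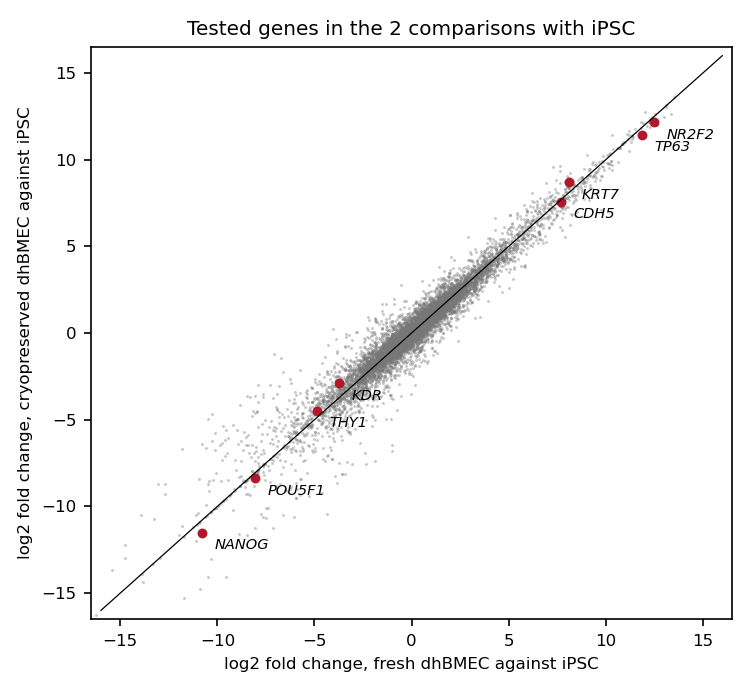
Each dot is 1 of the 17813 tested genes, with its log2 fold change in fresh dhBMECs against iPSCs (horizontal) and in cryopreserved dhBMECs against iPSCs (vertical), both against the same 3 iPSC libraries. The line marks equal change, and the 8 named genes lie close to it, from NANOG (-10.78 and -11.52) to NR2F2 (12.48 and 12.17).

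The comparison of cryopreserved with fresh dhBMECs asked what 1 year of frozen storage changed. No single gene passed the threshold of the edgeR test. With edgeR 0 of 17813 genes were called, 683 had an unadjusted p below 0.05 (891 expected by chance), limma-voom called 0 and DESeq2 called 20. Of the DESeq2 calls 8 were higher and 12 lower in cryopreserved dhBMECs. The keratins KRT8, KRT18 and KRT7 did not overlap between the groups, as 10% of genes do by chance. KRT8 was at 4537 ± 259 CPM in fresh and 6352 ± 903 CPM in cryopreserved dhBMECs (SD, n = 3 each), a log2 fold change of 0.49 ± 0.14 (SE; edgeR adjusted p = 0.996). KRT18 (0.57 ± 0.16) and KRT7 (0.60 ± 0.20) had similar values with adjusted p = 0.996. CDH5 was at 29.4 ± 8.21 and 27.6 ± 21.2 CPM (-0.09 ± 0.47, 95% interval -1.14 to 0.96), SLC2A1 at 671 ± 187 and 609 ± 34.8 CPM (interval -0.57 to 0.29) and CDH1 at 1413 ± 214 and 1307 ± 251 CPM (interval -0.51 to 0.29). ABCB1 (interval -1.78 to 1.41), ABCG2 (-1.54 to 1.31), KDR (-0.79 to 2.44), CLDN5 (-4.41 to 0.96) and NANOG (-3.25 to 1.76) left room for changes of more than 2-fold in at least 1 direction. OCLN (-0.82 to 0.33), TJP1 (-0.74 to 0.38), EPCAM (-0.24 to 0.36), POU5F1 (-0.90 to 0.26) and MKI67 (-0.86 to 0.49) had intervals within a 2-fold band, and SOX2 (-1.21 to 0.30), VWF (-0.13 to 2.05), CDKN1A (-0.34 to 1.64) and CYP26A1 (-0.67 to 2.49) crossed its edge, as did TFRC (-0.47 ± 0.24) and HMOX1 (0.14 ± 0.51). No call changed for these genes under any alternative, but the sign of the difference turned in at least 1 of them for POU5F1, NANOG, CDH5, KDR, CLDN5, OCLN, TJP1, SLC2A1, ABCB1, ABCG2, EPCAM, CDH1, MKI67 and HMOX1.

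Several genes with the lowest p in their lists were higher in cryopreserved dhBMECs, none of them past the threshold. Some lists leaned the other way, with 9 of 11 efflux transporters and 10 of 12 DNA methylation genes lower, also none past the threshold. Genes from the higher side were as follows. TGM2, a retinoic acid target, was at 75.0 ± 30.5 and 246 ± 137 CPM (log2 fold change 1.71 ± 0.43), CLDN10 at 17.6 ± 5.46 and 38.1 ± 12.2 CPM (1.11 ± 0.29), PDGFRB at 16.7 ± 3.35 and 40.1 ± 23.3 CPM (1.26 ± 0.38) and TUBB3 at 75.3 ± 19.6 and 154 ± 85.1 CPM (1.04 ± 0.35). The basement membrane collagens COL4A1 (0.70 ± 0.22) and COL4A2 (0.72 ± 0.24) and the glycolytic regulator PFKFB3 (0.55 ± 0.14) had smaller differences. All 7 had an edgeR adjusted p of 0.996. Cryopreserved replicate 2 held the highest level of TGM2, CLDN10, PDGFRB (67.0 against 25.8 and 27.5 CPM), TUBB3 (248 against 135 and 81.0 CPM), COL4A1 and COL4A2. Without it and fresh replicate 2, the libraries farthest apart on the second component, the log2 fold changes were 1.09 for TGM2, 0.61 for CLDN10, 0.64 for PDGFRB, 0.34 for TUBB3, 0.35 for COL4A1 and 0.24 for COL4A2. PNMA2 had the smallest adjusted p (0.237), at 0.114 ± 0.0319 CPM in fresh and 0.655 ± 0.102 CPM in cryopreserved dhBMECs, against 13.9 ± 1.47 CPM in iPSCs. It was chosen after its values were seen, and DESeq2 called it (log2 fold change 2.52, adjusted p = 7.66e-04, range 7.66e-04 to 1 over the alternatives).

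Across lists, 5 of 29 passed the camera test, all toward higher levels in cryopreserved dhBMECs. None of the 5 calls held with an estimated correlation, where the smallest adjusted p of the 5 was 0.795, and fry called 0 lists (smallest adjusted p = 0.879). Cholesterol synthesis genes had a median log2 fold change of 0.38 (camera adjusted p = 8.39e-04), with FDFT1 at 160 ± 4.80 and 241 ± 50.7 CPM, LDLR at 57.0 ± 7.96 and 85.1 ± 4.32 CPM, and FDPS at 77.4 ± 10.8 and 109 ± 5.65 CPM. The p53 targets had a median of 0.37 (8.39e-04), with AEN at 41.4 ± 2.93 and 54.7 ± 4.98 CPM, TNFRSF10B at 79.6 ± 7.55 and 110 ± 29.3 CPM and FDXR at 32.1 ± 4.81 and 42.6 ± 8.51 CPM. YAP and SRF targets had a median of 0.23 (0.00828), with ANKRD1 at 21.6 ± 6.33 and 35.0 ± 4.81 CPM, AXL at 154 ± 41.5 and 232 ± 79.9 CPM and TPM2 at 75.5 ± 24.7 and 119 ± 39.0 CPM. Oxidative stress genes had a median of 0.17 (0.035), with PRDX1 at 174 ± 51.3 and 237 ± 41.8 CPM and NQO1 at 12.4 ± 4.69 and 19.3 ± 4.69 CPM. Hypoxia and glycolysis genes had a median of 0.13 (0.035), with P4HA1 at 45.1 ± 1.85 and 65.5 ± 18.8 CPM, and 1 member, PFKFB3, passed when adjusted over the list alone. No member of any other list passed adjusted over the list alone. The mean log2 level of the p53 list relative to the 6 dhBMEC libraries was 0.50 in cryopreserved replicate 2, the library that stood apart on the second component, and between -0.24 and 0.03 in the other 5.

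Single libraries moved these calls. The p53 call was lost without cryopreserved replicate 2 (camera adjusted p = 0.141, range 1.03e-05 to 0.141). The oxidative stress call was lost without fresh replicate 2 (0.258) and cryopreserved replicates 2 (0.0601) and 3 (0.103), in a range of 0.0246 to 0.522. The hypoxia call was lost without fresh replicates 2 (0.135) and 3 (0.194) and cryopreserved replicate 3 (0.198), in a range of 0.027 to 0.198. The YAP call was lost without fresh replicate 1 (0.052) and cryopreserved replicate 1 (0.0923), in a range of 0.00283 to 0.0923. The cholesterol call stayed below 0.05 without each of the 6 libraries (range 3.93e-05 to 0.028).

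The other 24 lists did not pass in this comparison. Their camera adjusted p were 0.0624 for epithelial genes, 0.0772 for unfolded protein response, 0.111 for neural crest and placode, 0.128 for immediate early genes, 0.170 for pluripotency and for efflux transporters, 0.221 for epithelial-mesenchymal transition and for DNA methylation, 0.304 for cell cycle, 0.393 for Wnt targets, 0.413 for interferon, 0.473 for mesenchymal markers and for mitochondrially encoded genes, 0.493 for blood, 0.516 for nutrient transporters, 0.641 for receptor-mediated transcytosis, retinoic acid response and neural genes, 0.649 for choroid plexus, 0.672 for basement membrane, 0.708 for heat shock, 0.774 for junctions, 0.865 for inflammation and 0.901 for endothelial genes. Several of these crossed 0.05 in an alternative, in both directions. Without fresh replicate 1 these were Wnt targets (0.0316, lower in cryopreserved dhBMECs), unfolded protein response (0.0316, higher) and immediate early genes (0.0362, higher). Without fresh replicate 2 they were cell cycle (0.00874) and interferon (0.00203), both lower, and without fresh replicate 3 pluripotency (0.00504, lower) and epithelial genes (0.028, higher). Without cryopreserved replicate 1 they were retinoic acid response (0.0159, higher), unfolded protein response (0.0245, higher) and mitochondrially encoded genes (3e-06, lower), and without cryopreserved replicate 3 cell cycle (0.0025, lower) and epithelial-mesenchymal transition (0.0155, higher). With passage as a covariate they were epithelial genes (0.0466) and unfolded protein response (0.0442), both higher, and without both extreme libraries junctions (0.0305, higher) and interferon (0.0231, lower). All these values used the preset correlation, whereas the correlation estimated for the mitochondrially encoded list was 0.851. Median and mean differed in sign for junctions (-0.05 and 0.03), neural crest and placode (-0.17 and 0.03) and basement membrane (-0.04 and 0.03), and for inflammation the test direction was up with a median of -0.04.

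How closely the dhBMEC groups matched was limited by the spread of 3 libraries each. The 95% interval of the log2 fold change lay within a 2-fold band for 10943 genes (61.4%), and for 9368 (88.7%) of the 10563 genes with a mean of at least 10 CPM. Within a 1.5-fold band it lay for 5980 (33.6%). In simulated data with these depths and spreads over 17504 genes, edgeR found 1.5% of genes changed by 1.5-fold, 20.8% of those changed by 2-fold and 66.5% of those changed by 4-fold. The simulated means were taken over all libraries, iPSCs included, so these shares need not hold for genes expressed mainly in iPSCs. Frozen libraries carried date codes about 1 year before the fresh ones, so storage could not be told apart from the date of differentiation.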

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

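Most results kept their direction and side of the threshold. For named genes, 1344 of 1375 values were the same in fresh dhBMECs against iPSCs, 1172 of 1200 in cryopreserved dhBMECs against iPSCs and 598 of 628 in cryopreserved against fresh dhBMECs. For lists it was 336 of 377, 313 of 348 and 277 of 348. Gene counts in the 2 comparisons with iPSCs were 9938 and 9846 with DESeq2, 9254 and 9179 with limma-voom, 8925 and 8793 with no filter, and 6452 and 6379 at an adjusted p below 0.01. Requiring a 2-fold change left 5987 and 5955, and glmTreat against 1.5-fold left 5689 and 5614, as stricter thresholds must. For cryopreserved against fresh dhBMECs DESeq2 called 20 genes and every other alternative 0. Without 1 library the counts were 7751 to 9157, 7632 to 8248 and 0. DESeq2 gave no adjusted p for 3738, 3738 and 5592 genes. Of the alternatives chosen after seeing the data, leaving out both libraries extreme on the second component gave 9535, 9591 and 0 genes and 14, 15 and 4 lists, and halving all counts gave 9052, 8902 and 0 genes.

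With an estimated correlation camera called 0, 0 and 0 lists. Fry called 28, 28 and 0 lists in its mixed form and 19, 20 and 0 in its directional form. It tests each list against no change and not against other genes. Without 1 library, camera called 3 to 7 lists in cryopreserved against fresh dhBMECs. With the title number as a block there were 8720, 8625 and 0 genes and 14, 14 and 5 lists. The block brought the interferon list (0.0369) and HMOX1 (0.048) past the threshold in fresh dhBMECs, and took EPCAM (0.0553) and ABCB1 (0.0629) out of it in cryopreserved dhBMECs against iPSCs. It changed no other call of a list or named gene. Deviations of libraries with equal number correlated at 0.068, -0.029 and -0.03 between cryopreserved dhBMECs and iPSCs. Between cryopreserved and fresh dhBMECs they correlated at -0.066, -0.047 and -0.029, so the numbers gave no pairing in these comparisons. With only the 6 compared libraries, fresh dhBMECs against iPSCs had 8557 genes, and CLDN5 (0.0403), HMOX1 (0.0297) and EPCAM (0.0499) passed. Passage as a block on those 6 gave 7454 genes and 13 lists, with CLDN5 at 0.0402 and HMOX1 at 0.00375.

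Distance ratios against iPSCs were 2.69 and 2.79 over all tested genes and 4.10 and 4.24 with a prior count of 0.5. Without 1 library they were 4.52 to 5.88 and 4.81 to 5.77, and 0.861 to 0.993 between the dhBMEC groups. The correlation of fold changes was 0.987 over genes with at least 10 CPM and 0.964 to 0.965 without 1 iPSC library. A 1.5-fold band held 5980 genes in place of 10943, as a narrower band must, and limma-voom put 11093 inside the 2-fold band.

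Signs turned for genes that were not called, and the cause was not tested. KRT14, chosen after its values were seen, was at 0.11 with the block and 0.53 with limma-voom in fresh dhBMECs, and at 0.25 with the passage covariate and 0.39 without both extreme libraries in cryopreserved dhBMECs against iPSCs. Without both extreme libraries, cryopreserved against fresh dhBMECs gave 0.083 for POU5F1, 0.11 for CDH5, 0.12 for OCLN, 0.22 for TJP1, 0.51 for ABCB1, 0.33 for ABCG2, -0.072 for EPCAM, 0.12 for CDH1 and 0.29 for MKI67. Without 1 library the ranges were -0.549 to 0.006 for OCLN and -1.28 to 0.72 for KRT14 in fresh dhBMECs against iPSCs, and -0.068 to 0.314 for TJP1, -0.28 to 0.40 for MKI67 and -3.47 to 1.24 for KRT14 in cryopreserved dhBMECs against iPSCs. In cryopreserved against fresh dhBMECs they were -2.51 to 1.62 for NANOG, -0.93 to 0.25 for CDH5, -0.49 to 1.29 for KDR, -2.906 to 0.076 for CLDN5, -0.386 to 0.035 for OCLN, -0.328 to 0.077 for TJP1, -0.313 to 0.092 for SLC2A1, -1.22 to 0.30 for ABCB1, -0.43 to 0.11 for ABCG2, -0.051 to 0.145 for EPCAM, -0.273 to 0.006 for CDH1, -0.587 to 0.092 for MKI67 and -0.46 to 0.54 for HMOX1. The ends for NANOG and the lower end for CLDN5 rest on 2 counts in 1 group.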

Other observations

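The tests of an estimated correlation, of leaving out both extreme libraries, of depth and of HOX paralog groups were chosen only after the result was seen. The further endothelial markers and the amnion, trophoblast, mesothelium and surface ectoderm lists were written before they were tested, but after the report's values were seen. None of these 5 lists shares a gene with a list of the report, while the HOX list of groups 1 to 5 shares 9 genes with the retinoic acid list.

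HOX genes, which pattern the body axis, were higher in dhBMECs. All 12 tested genes of groups 1 to 5 were called higher in both dhBMEC groups, with HOXA1 at 120 ± 59.8 CPM, HOXB1 at 140 ± 12.8 CPM and HOXB2 at 95.4 ± 22.8 CPM in fresh dhBMECs (SD, n = 3). Of 16 genes in groups 9 to 13 only 3 had enough counts to test and 2 were called higher in both, HOXB9 and HOXC13 (5.17 ± 0.0501 CPM), while HOXB13 was not called (adjusted p = 0.485). Among tested genes, 12 of 12 against 2 of 3 gave a two-sided Fisher exact p of 0.2, which cannot decide the question. HOX genes near 0 counts in iPSCs passed the count filter only where dhBMECs expressed them. Genes that stayed silent were thus not compared. Of all listed genes, 12 of 15 in groups 1 to 5 and 2 of 16 in groups 9 to 13 were called higher in both. In these groups 3 and 13 genes had too few counts to test. Retinoic acid acting first on the 3' end of the clusters may explain the rises, which stayed open with 3 tested genes in groups 9 to 13 and no culture without retinoic acid.

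The keratin, TFAP2A, TP63, HAND1 and collagen transcripts raised the question of which cells the dhBMEC cultures held. Markers called higher in both dhBMEC groups were 9 of 9 for amnion, 10 of 11 for trophoblast, 9 of 10 for surface ectoderm and 4 of 8 for mesothelium, against 23.6% of all tested genes. Markers near 0 counts in iPSCs, such as ELF5 (0), HSD3B1 (2) and VGLL1 (2), passed the count filter only through dhBMEC expression. For these a call of higher was nearly fixed, so 23.6% is not a like baseline. Camera gave adjusted p of 1.54e-05, 5.58e-04, 2.03e-04 and 0.0194 in fresh dhBMECs, and 0.0910, 0.209, 0.0991 and 0.155 with an estimated correlation. The most abundant in fresh dhBMECs were IGFBP3 (550 ± 25.8 CPM), TBX3 (437 ± 15.5) and GABRP (353 ± 60.5) for amnion, CGA (232 ± 144) and PGF (152 ± 93.8) for trophoblast, PERP (401 ± 57.9) and COL17A1 (141 ± 45.1) for surface ectoderm and BNC1 (97.9 ± 10.4) for mesothelium. In cryopreserved dhBMECs CGA was at 139 ± 134 CPM and GABRP at 504 ± 477 CPM. The mesothelium marker WT1 (edgeR adjusted p = 0.387) and the surface ectoderm marker KRT14 (0.737) were not called in fresh dhBMECs. Mesothelium had the fewest abundant markers, with 2 of 8 at 10 CPM or more in fresh dhBMECs. The counts were 9 of 9 for amnion, 9 of 11 for trophoblast and 5 of 10 for surface ectoderm. Cells with amnion, trophoblast, surface ectoderm or mesothelium genes may be present, but the 4 lists were not told apart. The cells were not sorted, and bulk counts cannot say whether 1 cell carries several programs.

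The 5 lists higher in cryopreserved than in fresh dhBMECs were weighed against 2 technical explanations. Correlation between members stayed open as an explanation. The estimated correlations of the 5 lists were 0.166 to 0.896, above the preset 0.01. The smallest adjusted p of the 5 was 0.795 with an estimated correlation, but that setting called 0 lists in every comparison. For neural crest and placode genes in cryopreserved dhBMECs against iPSCs the estimate was -0.00491, below the preset value. The unadjusted camera p of that list still rose from 9.89e-04 to 0.013. A call lost in that setting thus cannot show that correlation caused it. Without both libraries extreme on the second component, cholesterol synthesis and YAP targets kept a camera adjusted p of at most 0.025 at the preset correlation. Their medians went from 0.38 to 0.34 and from 0.23 to 0.26, so these differences did not rest on those libraries alone. The kept p-values cannot exclude those libraries as a cause of the calls. Neither call held with an estimated correlation (camera adjusted p = 0.833 and 0.795). For p53 targets and oxidative stress both libraries could account for part of the difference. Without them both calls were lost (camera adjusted p = 0.0687 and 0.522), and the medians went from 0.37 to 0.12 and from 0.17 to 0.09. The mean log2 level of the oxidative stress list was -0.45 in fresh replicate 2 and between 0.03 and 0.13 in the other dhBMEC libraries. For hypoxia the question stayed open, as the call was lost (0.0687) but the median went only from 0.13 to 0.09. An effect of freezing could not be told apart from the date of differentiation.

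Some endothelial transcripts lay mostly in fresh dhBMEC replicate 1. It held 51 of 53 fresh counts of PECAM1, and, among genes chosen after their values were seen, 82 of 82 of PLVAP and 46 of 52 of SOX17. Its depth was 0.955 times the mean of the other dhBMEC libraries, which excludes depth. A small number of endothelial cells in that culture may explain it, yet of 12 further markers with enough counts 4 were highest there (33.3%, 16.7% by chance, exact one-sided binomial p = 0.125), with CD93 at 80 of 84 and CD34 at 18 of 24 dhBMEC counts. This stayed open.

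In the 10 splits of 6 libraries, which cannot give a p below 0.1, the real grouping called the most genes in fresh dhBMECs and in cryopreserved dhBMECs against iPSCs (1 split of 10 each, highest other 0), and 10 of 10 splits called 0 genes in cryopreserved against fresh dhBMECs. For lists 2, 3 and 4 of 10 splits called as many, up to 13, 15 and 10 lists. For genes with the interval inside a 2-fold band 3 of 10 splits reached the real 10943, up to 11017. The keratin gene KRT5, chosen after its values were seen, had 5 counts over the iPSC, 3 over the fresh and 362 over the cryopreserved libraries. Of the latter 284 were in cryopreserved replicate 1. It had too few counts for the main edgeR test. DESeq2 called it in cryopreserved against fresh dhBMECs (log2 fold change 6.83 ± 1.43, SE, adjusted p = 0.007), and edgeR with no filter called 0 genes there.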
